A study of Mus musculus with 12 samples.

How the data were processed

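Gene expression was measured on 12 mouse Affymetrix arrays, 1 per sample of sorted CD8 T cells. The labels give 3 groups: naive cells from spleen (n = 5), and PD-1+ Tim-3- (n = 3) and PD-1+ Tim-3+ (n = 4) tumour-infiltrating lymphocytes (TIL) from B16F10-GP melanoma. Per the labels, the Tim-3- sort was also 2B4- and the Tim-3+ sort 2B4+. The deposited values are linear intensities per probe set, with medians between 58.8 and 63.0 over the 12 arrays, and the log2 of each value was taken. The labels name RMA and the affy package. Their versions, the step back to the linear scale, and whether all arrays were normalized together are not given in the sources used here. The number of arrays limits the precision.

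The table holds 45101 probe sets, of which 64 are array controls. The array's annotation names exactly 1 gene for 34945 probe sets, several for 932 and none for 9160. A gene took the value of its probe set with the highest mean over all arrays, among probe sets naming only that gene. This gave 18193 genes, of which 9010 had more than 1 probe set. No filter on dim genes was applied. The values come without detection calls. A group mean below log2 5.71, percentile 40 of the tested genes, may lie at background, and a log2 change against it is then at best a lower bound.

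Each comparison was a contrast of 1 limma fit (version 3.58.1, R 4.3.3) of the 3 group means over all 12 arrays, with default empirical Bayes moderation and two-sided tests. Benjamini-Hochberg adjusted p below 0.05 over the 18193 genes is the threshold. Log2 changes are given ± SE from that fit. Group levels are mean log2 intensities ± SD. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

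A total of 29 gene lists with 622 members was fixed, of which 562 members were measured. The lists cover T cell states (stem-like and memory, inhibitory receptors, cytotoxic effector, exhaustion and effector transcription factors, costimulatory receptors, cytokine receptors, migration and residency, TCR signalling) and processes (mitosis, DNA replication, type I interferon response, glycolysis, oxidative phosphorylation, hypoxia, cholesterol synthesis, unfolded protein and integrated stress response, cytosolic ribosome). The rest are the sort markers, a list of dissociation and immediate early genes, and markers of other cells: melanoma, monocyte and macrophage, dendritic cell, neutrophil, B cell, NK cell, CD4 and regulatory T cell, erythroid, fibroblast and endothelium, and keratinocyte. The lists came from general knowledge, not from these samples. All but the sort markers, 28 lists, were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera was repeated with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone.

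The genes named were set by a rule: the sort markers; the 6 largest rises and 6 largest falls among genes past the threshold whose arrays did not overlap between groups; up to 3 members of each T cell state or process list with the smallest adjusted p below 0.05; up to 2 members of every other list with the highest mean; and 20 fixed genes, of which 16 were measured and the others are not reported here. Antigen receptor segments were left out of the largest changes. Genes named outside this rule are said to be. The rule picked 155 genes, and the text leaves some of them out. Between the TIL groups these include Ubash3b and Nfatc2, whose calls were lost in 7 of 7 and 5 of 7 fits without 1 array. Counts over named genes in the closing section take in all genes the rule picked. The groups, comparisons, lists, naming rule and alternatives were chosen before the data were examined, unless stated otherwise.

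Within groups, deviations from the group mean put the arrays into 2 sets, A and B, which the labels do not name but which hold the lower and the higher replicate numbers. Fits with the sets as a block, and within each set, were added after seeing the data. Alternatives fixed beforehand were the value per gene, normalization, a filter on dim genes at percentile 40, array weights, moderation with trend, fits of only the groups compared, the replicate number as a block, a minimum of 2-fold, other list tests, and leaving out each array in turn. Their effect is given in the closing section.

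The method was tested on simulated data drawn for each gene independently from its own mean and residual SD. Of 50 genes given a log2 change of 0.5, 34.0% were recovered for Tim-3+ against Tim-3- TIL, 30.0% for Tim-3- TIL against naive and 28.0% for Tim-3+ TIL against naive. At a log2 change of 1 the shares were 88.0%, 88.0% and 92.0%, and at 4 all were recovered. False calls made up 5.33%, 5.92% and 7.51% of calls, and runs without any change gave 0 calls by limma. For Tim-3+ against Tim-3- TIL, camera recovered the list that was shifted and called 0 of 20 lists that were not. Since these genes are not correlated, this does not test the preset correlation.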

Results

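Gene expression was measured on 12 mouse arrays of sorted CD8 T cells: 5 of naive cells from spleen, 3 of PD-1+ Tim-3- TIL and 4 of PD-1+ Tim-3+ TIL from B16F10-GP tumours, a skin melanoma grown in the flank. The labels call the Tim-3- cells stem-like and the Tim-3+ cells exhausted. All values below have n = 5 naive, 3 Tim-3- and 4 Tim-3+ arrays. Log2 intensities of arrays of 1 group correlated across genes with r between 0.988 and 0.996, arrays of the TIL groups with r between 0.970 and 0.982, and naive with TIL arrays with r between 0.921 and 0.950. Genes are not independent replicates. The first principal component held 73.4% of the variance and parted naive from TIL arrays, with Tim-3- arrays between naive and Tim-3+ arrays. The second held 11.4% and also parted the TIL groups.

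Arrays of every group also fell into 2 sets, which no label names but which part the lower from the higher replicate numbers in each group. Set A, the first 5 samples in the deposited order, held naive replicates 1 and 2, Tim-3- replicate 1 and Tim-3+ replicates 1 and 2, and set B held the other 7 arrays. The SD of log2 differences between arrays of 1 group lay between 0.234 and 0.301 within a set and between 0.337 and 0.412 across sets. The sets were drawn from these same values, so part of that gap is built in. The 3' minus 5' signal of 5 control transcripts, which reads RNA quality and amplification, averaged 0.22 ± 0.15 (SD) in naive, 0.23 ± 0.091 in Tim-3- and 0.13 ± 0.18 in Tim-3+ arrays. Centred on each group's mean, it was -0.145 in set A and 0.103 in set B. Values with the sets as a block, and within each set, therefore stand beside the results. In set A, 1 group has a single array, which is assumed to vary like the others.

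**Figure D1:**
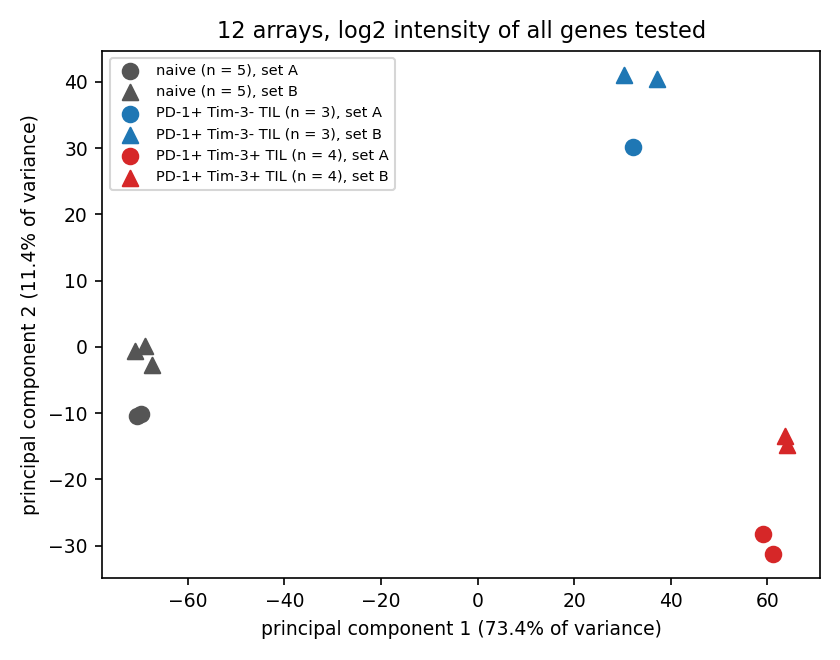
Principal components of log2 intensity over all genes tested, 1 point per array, with the share of variance on each axis; colour gives the group and shape the set. Naive and TIL arrays part on the first component (73.4%), where Tim-3- arrays lie between naive and Tim-3+ arrays. The TIL groups also part on the second (11.4%), and set A lies below set B in each group.

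The genes of the markers used for sorting were read first. Pdcd1, which encodes PD-1, had a log2 level of 5.14 ± 0.31 in naive, 11.38 ± 0.089 in Tim-3- and 11.77 ± 0.17 in Tim-3+ cells, and the TIL groups differed by 0.39 ± 0.17 (adjusted p = 0.152), short of the threshold. Havcr2, which encodes Tim-3, stood at 4.63 ± 0.23, 7.08 ± 0.49 and 11.66 ± 0.14, 23.8-fold higher in Tim-3+ than in Tim-3- cells (log2 change 4.58 ± 0.20, adjusted p = 4.56e-09). It was also higher in Tim-3- cells than in naive cells, by 2.45 ± 0.19 (adjusted p = 1.88e-07). Cd244a, which encodes 2B4, stood at 4.19 ± 0.30, 4.89 ± 0.77 and 11.49 ± 0.54, a log2 change of 6.61 ± 0.33 between TIL groups (adjusted p = 2.21e-08). Its level in Tim-3- cells differed from naive by 0.70 ± 0.32 (adjusted p = 0.110), 0.74 with the sets as a block (adjusted p = 0.0201), 1.52 within set A and 0.30 within set B. Set A has only Tim-3- replicate 1, at 5.77, while replicates 2 and 3 lay at 4.54 and 4.35 and naive arrays reached 4.62. Cd8a lay at 12.82 ± 0.035, 12.63 ± 0.027 and 12.85 ± 0.081, with no change past the threshold. Cd8b1 was lower in TIL, with log2 changes of -0.76 ± 0.099 in Tim-3- and -0.70 ± 0.091 in Tim-3+ cells against naive. Of the 5 markers, 2 rose from Tim-3- to Tim-3+ TIL over all genes and 4 adjusted over the list alone. Against naive, 2 rose and 1 fell in Tim-3- TIL (3 and 2 adjusted over the list alone), and 3 rose and 1 fell in Tim-3+ TIL (3 and 1).

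**Figure D2:**
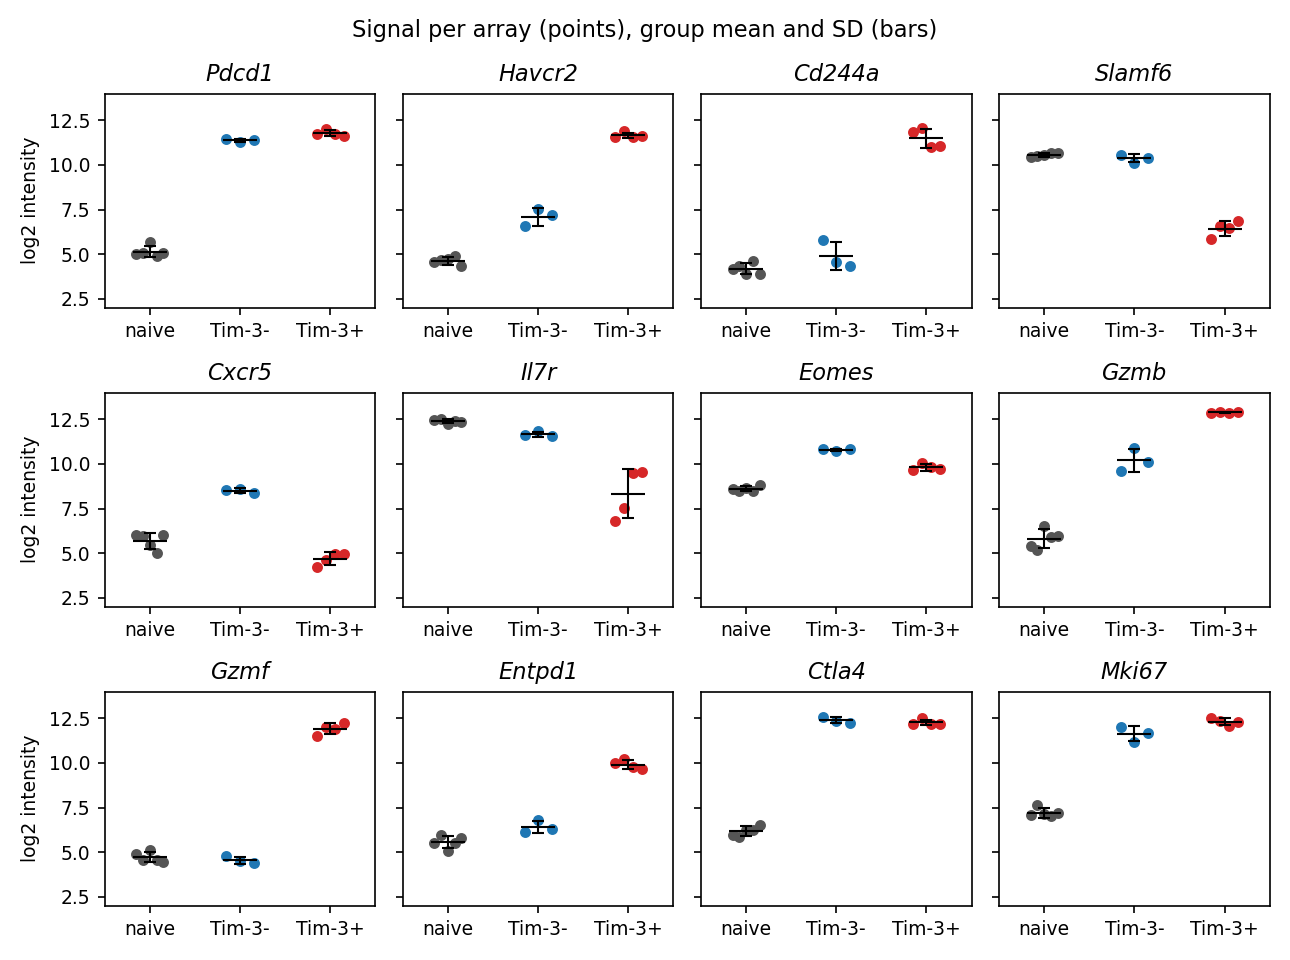
Log2 intensity of 12 genes on each array (points), with group mean and SD (bars), in naive (n = 5), Tim-3- (n = 3) and Tim-3+ (n = 4) cells. Gzmf and Cd244a are high in Tim-3+ cells, Slamf6 and Il7r are low there, Cxcr5 peaks in Tim-3- cells, and Ctla4 is high in both TIL groups.

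Tim-3+ TIL were compared with Tim-3- TIL to ask how PD-1+ cells that carry the exhaustion markers differ from those that lack them. Several granzyme genes, which encode proteases of cytotoxic granules, rose in Tim-3+ cells. Gzmf went from 4.54 ± 0.20 to 11.91 ± 0.31, and Gzmd and Gzme rose by 7.14 ± 0.27 and 6.46 ± 0.25. In Tim-3- cells all 3 lay below log2 5.71, percentile 40 of the tested genes, so these changes are at best lower bounds. Gzmk arrays of the TIL groups overlapped. S1pr1, a receptor for leaving tissue, fell from 10.22 ± 1.02 to 4.67 ± 0.71, the latter also below 5.71, and Slamf6, a surface marker of stem-like cells, fell from 10.37 ± 0.22 to 6.42 ± 0.42 (15.4-fold). The mitosis list rose by a median log2 change of 1.24 (camera adjusted p = 1.09e-24). It did not pass when the correlation was estimated (adjusted p = 0.0740 with an estimated correlation).

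Of 18193 genes, 2463 passed the threshold, 1413 higher and 1050 lower in Tim-3+ cells, and 775 of them changed at least 2-fold (373 higher, 402 lower). With the sets as a block, 3348 passed (1964 higher, 1384 lower), among them 2461 of the 2463 with the same sign. Within set A 1590 passed, and within set B 2175. The arrays of the groups did not overlap for 22.7% of genes, where chance gives 5.71%. Besides Cd244a and the granzymes, the largest rises were the chemokine Ccl9 (5.08 ± 0.18) and Gm36723 (4.88 ± 0.25), and the largest falls were Aff3 (-6.21 ± 0.24), S1pr1 (-5.55 ± 0.41), Lrig1 (-5.11 ± 0.28), Nsg2 (-5.05 ± 0.19), Klf3 (-4.97 ± 0.24) and Dapl1 (-4.81 ± 0.25). Every gene named below as changed between the TIL groups had all Tim-3+ arrays on 1 side of all Tim-3- arrays. Cd244a, Gzmd, Gzme, Gzmf, Ccl9, Ltf and Styk1 lay below 5.71 in Tim-3- cells. Aff3, S1pr1, Nsg2, Klf3, Cxcr5, Oasl2 and Tnfrsf25 lay below it in Tim-3+ cells.

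The stem-like and memory list fell as a group. Of its 27 measured members, 0 rose, 22 fell and 5 did not pass (0 and 24 adjusted over the list alone), with a median log2 change of -2.06 and camera adjusted p = 8.29e-29. The median was -2.02 with the sets as a block, -2.24 within set A and -2.03 within set B. The call held with an estimated correlation (adjusted p = 0.00976). Cxcr5, a chemokine receptor, fell by 3.82 on the log2 scale, the transcriptional repressor Bach2 changed by -2.31 ± 0.14, and Slamf6 by -3.94 ± 0.19 (adjusted p = 1.25e-08). Il7r, the receptor for the survival cytokine interleukin 7, changed by -3.32 ± 0.51, Ccr7, a lymph node homing receptor, by -2.23 ± 0.25 and Id3 by -1.22 ± 0.13. Il7r changed by -4.43 within set A and -2.18 within set B. The chemokine gene Xcl1 also fell (-1.86 ± 0.54, adjusted p = 0.0357), but that call was lost without any 1 of Tim-3- replicates 1, 2 and 3 or Tim-3+ replicates 1, 2 and 3, with adjusted p between 0.0630 and 0.120.

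The cytotoxic effector list rose. Of 27 members, 12 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.63, 0.55 with the sets as a block, and 0.67 and 0.63 within sets A and B (camera adjusted p = 6.48e-09). The call held with an estimated correlation (adjusted p = 0.00976). Gzmb rose by 2.67 ± 0.30 to 12.88 ± 0.047. Ifng, which encodes interferon gamma, was higher by 1.18 ± 0.38 but short of the threshold (adjusted p = 0.0536). With the sets as a block it was at 1.17 (adjusted p = 0.0567), and within sets A and B at 0.85 and 1.253. Leaving out 1 array gave adjusted p between 0.0347, without Tim-3- replicate 1, and 0.190, without Tim-3- replicate 3. Besides leaving out arrays, Ifng passed in 8 of 13 alternatives, with adjusted p from 0.00971 to 0.0488. The 13 include the fits with the sets as a block and within each set, and none of the 8 is among these. Prf1, which encodes the pore-forming protein perforin, has 2 probe sets that differ. The brighter one, used for the gene, lay at 9.30 ± 0.22 in Tim-3- and 9.40 ± 0.31 in Tim-3+ cells (adjusted p = 0.821), whereas the other lay at 7.62 ± 0.13 and 10.89 ± 0.43, a difference of 3.28.

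The inhibitory receptor and transcription factor lists went both ways, and neither passed as a group (camera adjusted p = 0.867 and 0.867, medians -0.11 and 0.0069). The mean of the inhibitory list, 0.23, and its test had the opposite sign to its median. Of its 16 members, 5 rose and 3 fell (5 and 4 adjusted over the list alone). Entpd1, which encodes the ectoenzyme CD39, rose by 3.49 ± 0.21 and Cd200r1 by 3.56 ± 0.31, whereas Btla changed by -2.49 ± 0.15. Ctla4 was at 12.40 ± 0.16 in Tim-3- and 12.26 ± 0.16 in Tim-3+ cells (adjusted p = 0.705). Lag3 rose by 0.55 ± 0.13 (adjusted p = 0.00948), a call lost without Tim-3- replicate 2 (adjusted p = 0.0600) and within set A (0.28, adjusted p = 0.479). Of 22 transcription factors, 4 rose and 3 fell, with 4 and 3 also adjusted over the list alone: Prdm1, which encodes Blimp-1, rose by 2.04 ± 0.17 and Id2 by 1.04 ± 0.11, while Tox2 changed by -1.53 ± 0.16 and Eomes by -0.97 ± 0.12. Tox stood at 10.38 ± 0.61 and 10.69 ± 0.55 (adjusted p = 0.579).

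Both cell cycle lists rose at the preset correlation. In the mitosis list 32 of 33 members rose and 0 fell, by limma over all genes as adjusted over the list alone, with a median of 1.24, 1.20 with the sets as a block, 1.09 within set A and 1.31 within set B (camera adjusted p = 1.09e-24; adjusted p = 0.0740 with an estimated correlation). In the DNA replication list 24 of 31 rose (25 adjusted over the list alone), with medians of 0.78, 0.72, 0.62 and 0.84 in the same order (adjusted p = 8.72e-14; adjusted p = 0.0740 with an estimated correlation). The centromere histone Cenpa rose by 0.98 ± 0.11, the kinesin Kif20a by 1.15 ± 0.15, the condensin subunit Ncapg by 1.13 ± 0.15, the checkpoint gene Clspn by 1.34 ± 0.18 and the chromatin assembly gene Chaf1b by 1.27 ± 0.17. With the most variable of its probe sets, Cenpa was at 0.37 (adjusted p = 0.482). Mki67, which encodes the proliferation marker Ki-67, rose less (0.67 ± 0.20, adjusted p = 0.0345), and its call was lost without any 1 of Tim-3- replicates 2 and 3 or Tim-3+ replicates 1, 2 and 4 (adjusted p between 0.0628 and 0.187), and within set A, where it was at 0.41 (adjusted p = 0.399). With replicates as a block and in a fit of these groups alone its adjusted p was 0.0521 and 0.0627.

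Of metabolic and stress lists, 5 rose at the preset correlation and none passed with an estimated one. In glycolysis 9 of 17 members rose and 2 fell (12 and 2 adjusted over the list alone; median 0.39, camera adjusted p = 2.68e-05; adjusted p = 0.0740 with an estimated correlation). The glucose transporter Slc2a3 was at 1.62 ± 0.26 and the lactate transporter Slc16a3 at 1.11 ± 0.17. In cholesterol synthesis 8 of 16 rose (13 adjusted over the list alone; median 0.55, adjusted p = 1.58e-07; adjusted p = 0.0897 with an estimated correlation). Fdps was at 1.58 ± 0.17 and Lss at 0.96 ± 0.11. In hypoxia 7 of 23 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.26, adjusted p = 0.0101; adjusted p = 0.0740 with an estimated correlation). Bnip3 was at 1.81 ± 0.23 and Gbe1 at 1.59 ± 0.17. In oxidative phosphorylation 4 of 34 rose (3 adjusted over the list alone; median 0.14, adjusted p = 0.0101; adjusted p = 0.334 with an estimated correlation, and 0.0625 without Tim-3- replicate 2). In the unfolded protein and integrated stress response 6 of 27 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.16, adjusted p = 0.0471; adjusted p = 0.532 with an estimated correlation). Sdf2l1 was at 0.58 ± 0.11 (adjusted p = 0.0690 within set A). That last list call was lost without any 1 of Tim-3- replicates 1 and 2 or Tim-3+ replicates 3 and 4 (adjusted p up to 0.352), with quantile normalization again (adjusted p = 0.0890), with a filter on dim genes (0.139), with replicates as a block (0.128) and by limma's fry (0.0914). Within set A the oxidative phosphorylation and stress response calls were lost (adjusted p = 0.0954 and 0.0540). With the sets as a block the 5 medians were 0.38, 0.61, 0.29, 0.12 and 0.22, within set A 0.42, 0.65, 0.37, 0.13 and 0.35, and within set B 0.37, 0.60, 0.18, 0.13 and 0.24.

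The interferon response and 2 receptor lists fell at the preset correlation and did not pass with an estimated one or within set A. In the type I interferon response 10 of 27 members fell and 1 rose (10 and 1 adjusted over the list alone; median -0.27, camera adjusted p = 3.95e-06; adjusted p = 0.172 with an estimated correlation), with 16 not past the threshold. The antiviral genes Oas3, Oasl2 and Ifit3 were at -1.78 ± 0.15, -2.07 ± 0.22 and -2.09 ± 0.24. Of 14 costimulatory receptors 7 fell and 2 rose (8 and 3 adjusted over the list alone; median -0.34, adjusted p = 0.0111; adjusted p = 0.160 with an estimated correlation). Tnfrsf25 was at -1.54 ± 0.27 and Cd70 at -1.09 ± 0.20 against Cd226 at 1.32 ± 0.26. Of 23 migration and residency genes 7 fell and 3 rose (8 and 5 adjusted over the list alone; median -0.25, adjusted p = 0.0111; adjusted p = 0.172 with an estimated correlation). The chemokine receptor Cxcr3 was at -2.56 ± 0.20 and the integrins Itgb7 and Itgb1 at -1.99 ± 0.12 and -1.42 ± 0.10. The 3 medians were -0.27, -0.33 and -0.23 with the sets as a block, -0.22, -0.30 and -0.067 within set A, and -0.41, -0.42 and -0.32 within set B. Within set A alone the 3 calls were lost (adjusted p = 0.0540, 0.163 and 0.153). Lists not past the threshold were cytokine receptors (2 rose and 4 fell of 18, adjusted p = 0.347; Tgfbr3 -2.83 ± 0.44), TCR signalling (2 and 3 of 22, 0.256) and the cytosolic ribosome (0 and 0 of 27, 0.292). Adjusted over the list alone, the counts were 2 and 4, 4 and 6, and 0 and 0.

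Dissociation and immediate early genes fell slightly: 5 of 25 fell and 3 rose, the same counts adjusted over the list alone, with a median of -0.13, -0.13 with the sets as a block, and -0.19 and -0.26 within sets A and B (camera adjusted p = 0.0277). The call was lost without Tim-3- replicate 1 or Tim-3+ replicate 4 (adjusted p between 0.0655 and 0.0888), and adjusted p = 0.334 with an estimated correlation. None of the 10 lists of other cells passed. The numbers that rose and fell, the same adjusted over the list alone, and camera adjusted p were: melanoma (0 and 0 of 16, 0.188), monocyte and macrophage (3 and 3 of 24, 0.853), dendritic cell (0 and 2 of 13, 0.256), neutrophil (1 and 0 of 10, 0.470), B cell (0 and 3 of 14, 0.0866), NK cell (4 and 1 of 8, 0.0748), CD4 and regulatory T cell (1 and 2 of 10, 0.797), erythroid (0 and 1 of 6, 0.529), fibroblast and endothelium (0 and 1 of 17, 0.504) and keratinocyte (0 and 1 of 10, 0.255). Melanoma markers passed without Tim-3- replicate 3 or Tim-3+ replicate 2 (adjusted p between 0.00990 and 0.0473), and NK cell markers without Tim-3- replicate 3 (adjusted p = 0.0473). NK cell markers passed with replicates as a block as well (0.0284), B cell markers with a filter on dim genes (0.0163). By fry, which tests each list without the other genes, B cell, NK cell and keratinocyte markers passed (0.0287, 0.00150 and 0.0193). Median and mean had opposite signs for the CD4 list (0.083 and -0.039) and for fibroblast and endothelium (0.033 and -0.065). Single members did change. Ltf, of the neutrophil list, rose by 3.26 ± 0.23, Fcer1g and Styk1, chosen after their values were seen, rose by 2.54 ± 0.23 and 3.33 ± 0.35, and Gzma rose by 1.36 ± 0.37. The Gzma call was lost without any 1 of Tim-3- replicates 1 and 3 or Tim-3+ replicate 2 (adjusted p up to 0.107), within set A (2.25, adjusted p = 0.0555), within set B (0.83, adjusted p = 0.225) and in a fit of these groups alone (adjusted p = 0.0517). Ighm, of the B cell list, changed by -2.004 ± 0.14, Pecam1 by -1.46 ± 0.13, Car2 by -2.10 ± 0.27, and Cd74 by -1.62 ± 0.41, the last lost without Tim-3- replicate 2 or 3 (adjusted p up to 0.0873) and within set A (-1.29, adjusted p = 0.104). The melanoma genes Pmel and Trpm1 were at 7.17 ± 0.26 and 7.53 ± 0.59 in Tim-3- and 6.81 ± 0.49 and 7.69 ± 0.16 in Tim-3+ cells.

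**Figure D3:**
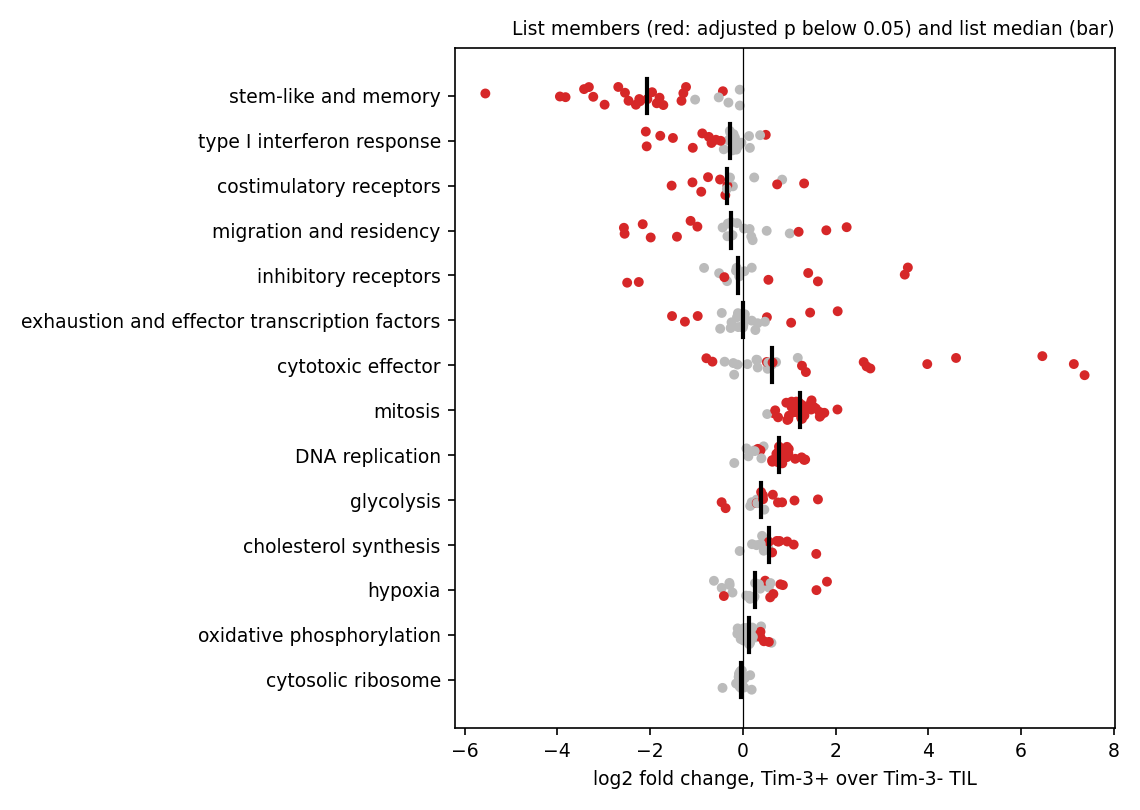
Log2 fold change of Tim-3+ over Tim-3- TIL for each measured member of 14 gene lists (points, red where adjusted p is below 0.05) and the list median (bar). The stem-like and memory list has the lowest median (-2.06) and the mitosis list the highest (1.24), while the inhibitory receptor and transcription factor lists have medians near 0 and members on both sides.

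Tim-3- TIL were compared with naive cells to ask what sets PD-1+ cells without the exhaustion markers apart from cells that have not met antigen. Klrc1, an inhibitory NK receptor, rose from 3.88 ± 0.51 to 11.90 ± 0.12, the transcription factor Bhlhe40 rose by 7.77 ± 0.23 and Ctla4 by 6.23 ± 0.15 (75.3-fold). Transcription factors of effector and exhausted cells rose by a median of 2.63, and mitosis genes by 2.91. Slamf6, Il7r and Ccr7, which mark naive and memory cells, did not pass the threshold in either direction in the fit of all groups. In a fit of Tim-3- and naive arrays alone, Il7r passed as lower and Ccr7 as higher in Tim-3- cells.

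In all, 6252 genes passed, 2926 higher and 3326 lower in Tim-3- TIL, and 2183 changed at least 2-fold (1272 higher, 911 lower). Blocking on the sets, 7319 passed, within set A 4371 and within set B 6432. Arrays did not overlap for 35.1% of genes (3.57% by chance). Further large rises were the calcium-binding protein S100a4 (7.33 ± 0.23), Nrn1 (7.28 ± 0.16), Plek (7.12 ± 0.11) and Tnfsf11, which encodes RANK ligand (7.05 ± 0.49). The largest falls were the gut homing receptor Ccr9 (-5.76 ± 0.15), Dtx1 (-5.05 ± 0.21), Cnr2 (-4.996 ± 0.15), Tmem108 (-4.90 ± 0.17), Nrp2 (-4.52 ± 0.15) and Lypd6b (-4.42 ± 0.22). Naive cells came from spleen and TIL from digested tumours passed over Percoll, so the cell state, the tissue and its handling cannot be told apart in the comparisons with naive cells. Genes named as changed here had all Tim-3- arrays on 1 side of all naive arrays. Many lay below 5.71 in the lower group, and their changes are at best lower bounds. Among them are Bhlhe40, S100a4, Nrn1, Plek, Tnfsf11, Ifng, Fasl, Zeb2 and Tox2 in naive cells and Ccr9, Cnr2, Tmem108, Nrp2 and Lypd6b in Tim-3- cells.

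The stem-like and memory list split: 11 of 27 members rose and 9 fell, the same counts adjusted over the list alone (median 0.28, camera adjusted p = 0.199). Cxcr5 rose by 2.82 ± 0.23, Xcl1 by 4.56 ± 0.52, the chemokine Cxcl10 by 4.97 ± 0.21 and the costimulatory receptor Icos by 2.27 ± 0.14, while Il6ra changed by -3.68 ± 0.20 and Id3 by -1.45 ± 0.13. Slamf6 lay at 10.55 ± 0.090 in naive and 10.37 ± 0.22 in Tim-3- cells (adjusted p = 0.475), Il7r at 12.41 ± 0.11 and 11.65 ± 0.15 (adjusted p = 0.264), and Ccr7 at 12.03 ± 0.12 and 12.46 ± 0.19 (adjusted p = 0.192). Slamf6 differed by 0.10 within set A and -0.34 within set B. In a fit of these groups alone, Il7r and Ccr7 did pass (-0.76, adjusted p = 3.45e-04, and 0.43, adjusted p = 0.0173), as they did within set B (-0.67, adjusted p = 0.00278, and 0.45, adjusted p = 0.0190). With its most variable probe set Il7r also passed (-1.55, adjusted p = 0.00846). The fit of all groups shares 1 estimate of the spread, which takes in the Tim-3+ arrays. These ranged from 6.81 to 9.54 for Il7r and from 9.49 to 10.78 for Ccr7. For both genes the Tim-3- and naive arrays did not overlap.

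Inhibitory receptors rose in 11 of 16 members and fell in 2 (11 and 3 adjusted over the list alone; median 1.51, camera adjusted p = 2.83e-08, 0.00932 with an estimated correlation), with Lag3 up by 4.56 ± 0.12 and Entpd1 by 0.85 ± 0.20 (0.41, adjusted p = 0.230, within set A). Transcription factors rose in 20 of 22 (20 up and 1 down adjusted over the list alone; adjusted p = 1.18e-18, 0.00932 with an estimated correlation): Zeb2 by 6.27 ± 0.19, Tox2 by 4.72 ± 0.16, Eomes by 2.19 ± 0.12, Tox by 1.57 ± 0.27 and Prdm1 by 1.38 ± 0.16. Cytotoxic effector genes rose in 20 of 27 and fell in 1 (20 and 2 adjusted over the list alone; median 0.91, adjusted p = 2.54e-10, 0.00346 with an estimated correlation), with Ifng up by 6.92 ± 0.36, the death ligand Fasl by 6.35 ± 0.23, Gzmk by 5.71 ± 0.20, the chemokine Ccl5 by 4.64 ± 0.18 and Gzmb by 4.41 ± 0.29. Prf1 fell (-0.60 ± 0.17, adjusted p = 0.0162), and that call was lost without Tim-3- replicate 2 or 3 (adjusted p up to 0.0877). Its other probe set differed by -0.54 (adjusted p = 0.0667).

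Further receptor lists rose too. Migration and residency genes rose in 14 of 23 members and fell in 6, the same adjusted over the list alone (median 1.45, camera adjusted p = 2.74e-05, 0.0327 with an estimated correlation), among them Itgb1 (3.70 ± 0.10) and Rgs1 (5.21 ± 0.14). Cytokine receptors rose in 12 of 18 and fell in 4, the same adjusted over the list alone (median 1.02, adjusted p = 5.06e-04; adjusted p = 0.127 with an estimated correlation). Il18rap was at 3.67 ± 0.18, the decoy receptor Il1r2 at 4.66 ± 0.24 and Il6st at -1.99 ± 0.11. Costimulatory receptors rose in 7 of 14 and fell in 3 (8 and 3 adjusted over the list alone; median 0.77, adjusted p = 0.00187; adjusted p = 0.0662 with an estimated correlation). Tnfrsf4, which encodes OX40, was at 4.25 ± 0.11 and Slamf7 at 3.23 ± 0.21. TCR signalling did not pass (5 rose and 7 fell of 22, adjusted p = 0.741; Sh2d2a 2.05 ± 0.11), with the same counts adjusted over the list alone.

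Lists of cell division and metabolism rose. Mitosis genes rose in 31 of 33 and fell in 1 (32 and 1 adjusted over the list alone; camera adjusted p = 6.12e-25, 0.0348 with an estimated correlation), with the cyclin Ccnb2 up by 4.91 ± 0.20, Mki67 by 4.42 ± 0.19 and Kif11 by 3.90 ± 0.17. DNA replication genes rose in 28 of 31, also adjusted over the list alone (median 1.18, adjusted p = 7.01e-17, 0.0327 with an estimated correlation), with Rrm2 at 4.13 ± 0.20 and Cdc6 at 4.87 ± 0.26. Glycolysis genes rose in 12 of 17, also adjusted over the list alone (median 0.64, adjusted p = 5.55e-07, 0.0317 with an estimated correlation), with hexokinase 2, Hk2, at 3.05 ± 0.12 and Tpi1 at 2.36 ± 0.18. The stress response list rose in 15 of 27 and fell in 4 (19 and 4 adjusted over the list alone; median 0.60, adjusted p = 7.97e-06; adjusted p = 0.127 with an estimated correlation). Asparagine synthetase, Asns, was at 4.29 ± 0.31. Oxidative phosphorylation genes rose in 8 of 34 (6 adjusted over the list alone; median 0.13, adjusted p = 0.00883; adjusted p = 0.287 with an estimated correlation). Hypoxia genes rose in 11 of 23 and fell in 5, the same adjusted over the list alone (median 0.36, adjusted p = 0.0477; adjusted p = 0.0911 with an estimated correlation). Hif1a was at 1.90 ± 0.12 and Pdk1 at -2.30 ± 0.092. The hypoxia call was also lost without any 1 of naive replicates 2, 3 and 5 or Tim-3- replicate 3 (adjusted p up to 0.0691), with the mean of all probe sets (0.0729), with quantile normalization again (0.0607), with replicates as a block (0.0533) and with a filter on dim genes (0.284). Oxidative phosphorylation lost its call with quantile normalization again (0.0607). Interferon response (5 rose, 10 fell of 27, adjusted p = 0.147; Usp18 -2.69 ± 0.20, Ifit2 -1.20 ± 0.13), cholesterol synthesis (6 and 5 of 16, 0.228; Insig1 1.35 ± 0.11) and the ribosome (1 and 3 of 27, 0.227) did not pass, with 5 and 11, 8 and 5, and 0 and 0 adjusted over the list alone. The interferon response passed without Tim-3- replicate 2 (adjusted p = 0.0327).

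List medians with the sets as a block, within set A and within set B were 1.53, 1.55 and 1.78 for inhibitory receptors, 2.64, 2.92 and 2.22 for transcription factors, 0.88, 1.01 and 1.03 for cytotoxic effector genes. They were 1.47, 0.87 and 1.84 for migration genes, 1.02, 1.17 and 1.04 for cytokine receptors, 0.77, 0.66 and 0.80 for costimulatory receptors, and 2.91, 3.04 and 2.77 for mitosis. For the other lists past the threshold they were 1.20, 1.254 and 1.13 for DNA replication, 0.67, 0.61 and 0.69 for glycolysis, 0.57, 0.52 and 0.55 for the stress response. Next came 0.14, 0.13 and 0.19 for oxidative phosphorylation, 0.34, 0.22 and 0.43 for hypoxia, 0.75, 0.99 and 0.77 for dissociation genes, 1.13, 1.37 and 1.18 for CD4 and regulatory T cell markers, and -0.38, -0.65 and -0.21 for B cell markers. The B cell call was lost within set B (adjusted p = 0.135) and with the mean of all probe sets (0.0537). All 15 lists past the threshold passed with the sets as a block.

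Dissociation and immediate early genes moved with these groups: 17 of 25 rose and 1 fell, the same adjusted over the list alone, with a median of 0.75 (camera adjusted p = 6.99e-08, 0.0317 with an estimated correlation). Nfkbia, an inhibitor of NF-kappaB, rose by 0.83 ± 0.11. Among lists of other cells, CD4 and regulatory T cell markers rose in 9 of 10 (10 adjusted over the list alone; median 1.14, adjusted p = 3.85e-09, 0.00333 with an estimated correlation). Of these, 4 stand in the T cell lists, and the lineage genes Cd4 and Foxp3, chosen after their values were seen, changed by 0.83 ± 0.13 and 0.85 ± 0.12 against 3.64 ± 0.21 for Ikzf2. B cell markers fell in 5 of 14 and rose in 1 (6 and 1 adjusted over the list alone; median -0.39, adjusted p = 0.0308; adjusted p = 0.328 with an estimated correlation), with Ighm at -1.44 ± 0.14 and Cd79b at -2.52 ± 0.12. The rest did not pass, with numbers risen and fallen and adjusted p of: melanoma (2 and 2 of 16, 0.741; Pmel -0.88 ± 0.23, Trpm1 -1.49 ± 0.25), monocyte and macrophage (2 and 2 of 24, 0.696), dendritic cell (4 and 1 of 13, 0.242; Cd74 2.80 ± 0.39), neutrophil (1 and 1 of 10, 0.905), NK cell (3 and 1 of 8, 0.0648; Gzma 3.52 ± 0.35), erythroid (1 and 0 of 6, 0.741; Car2 2.58 ± 0.26), fibroblast and endothelium (0 and 1 of 17, 0.393; Pecam1 -1.60 ± 0.13) and keratinocyte (1 and 0 of 10, 0.188; Perp 6.62 ± 0.20). Adjusted over the list alone the counts were 2 and 1 for monocyte and macrophage, 4 and 2 for dendritic cell, 1 and 0 for neutrophil, 4 and 1 for NK cell, and otherwise the same. Within sets A and B, Pmel was at -1.32 and -0.64, Trpm1 at -0.39 and -2.12, and Cd74 at 1.74 and 3.36. Pmel and Trpm1 did not pass within set A (adjusted p = 0.0965 and 0.183). Median and mean had opposite signs for the monocyte and macrophage (-0.028 and 0.089), neutrophil (-0.12 and 0.29) and erythroid (-0.079 and 0.35) lists. The melanoma genes Tyrp1 and Dct, chosen after their values were seen, rose by 3.05 ± 0.62 and 2.24 ± 0.58 and lay at 6.15 ± 1.03 and 6.33 ± 0.77. NK cell markers passed without Tim-3- replicate 2 (adjusted p = 0.0334) and with a filter on dim genes (0.0146). Lists past the threshold by fry but not by camera were NK cell (2.27e-05), keratinocyte (5.85e-07), fibroblast and endothelium (0.00354), interferon response (0.00981), ribosome (0.00981), stem-like and memory (0.0345) and cholesterol synthesis (0.0439).

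Tim-3+ TIL were compared with naive cells for the full distance from naive to exhausted cells. Ifng rose from 3.75 ± 0.79 to 11.85 ± 0.24, and Gzmd and Gzme rose by 8.04 ± 0.23 and 7.87 ± 0.22. The egress receptor S1pr1 and the transcription factors Klf3 and Klf2 were lower, with log2 changes of -7.14 ± 0.36, -7.06 ± 0.21 and -4.19 ± 0.16. All 33 mitosis genes measured rose, by a median of 4.31. In Tim-3- cells neither Slamf6 nor Il7r passed in the fit of all groups, though Il7r did without the Tim-3+ arrays. In Tim-3+ cells Slamf6 and Il7r fell by 4.13 and 4.08 on the log2 scale. Il7r changed by -5.34 within set A and -2.85 within set B.

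In all, 7554 genes passed, 3661 higher and 3893 lower in Tim-3+ TIL, and 2598 changed at least 2-fold (1501 higher, 1097 lower). Which direction held more genes turned with arrays centred on their medians (3967 higher, 3339 lower) and with a filter on dim genes (3290 and 3175). Blocking on the sets, 8717 passed, within set A 6210 (3124 higher, 3086 lower) and within set B 7244 (3647 and 3597). Arrays did not overlap for 37.3% of genes (1.59% by chance). Other large rises were S100a4 (8.24 ± 0.21), Klrc1 (8.21 ± 0.21) and Plek (7.73 ± 0.10), and other large falls Dtx1 (-6.87 ± 0.20), Aff3 (-6.72 ± 0.21), H2-Ob (-6.32 ± 0.31) and Nsg2 (-6.28 ± 0.17). As above, tissue and handling differ along with the cells. Genes named as changed here had all Tim-3+ arrays on 1 side of all naive arrays, except Prf1. Levels were below 5.71 for Ifng, Gzmd, Gzme, Gzmf, S100a4, Klrc1, Plek and others in naive cells. In Tim-3+ cells they were below it for S1pr1, Klf3, Dtx1, Aff3, H2-Ob, Nsg2, Il6ra, Oasl2 and Cd79b. Cxcr5 lay below it in both groups.

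The stem-like and memory list fell: 18 of 27 members fell and 6 rose, the same adjusted over the list alone (median -1.002, camera adjusted p = 3.99e-04, adjusted p = 0.209 with an estimated correlation). Il6ra changed by -6.22 ± 0.18, Rasgrp2 by -3.85 ± 0.15, Id3 by -2.68 ± 0.12, Ccr7 by -1.80 ± 0.22 and Cxcr5 by -1.002 ± 0.21 (-0.53, adjusted p = 0.136, within set B), while Xcl1 rose by 2.71 ± 0.48. Cytotoxic effector genes rose in 23 of 27 and fell in 2, the same adjusted over the list alone (median 3.15, adjusted p = 1.33e-14, 0.00174 with an estimated correlation), with Gzmf up by 7.20 ± 0.17 and Gzmb by 7.08 ± 0.26. The brighter Prf1 probe set fell (-0.50 ± 0.16, adjusted p = 0.0226), a call lost without any 1 of naive replicates 1 and 2 or Tim-3+ replicates 3 and 4 (adjusted p up to 0.0838), whereas the other differed by 2.74. Inhibitory receptors rose in 12 of 16 and fell in 4, the same adjusted over the list alone (median 2.88, adjusted p = 2.58e-06, 0.0137 with an estimated correlation): Ctla4 by 6.10 ± 0.14, Lag3 by 5.11 ± 0.11 and Entpd1 by 4.34 ± 0.18. Transcription factors rose in 20 of 22 and fell in 1, the same adjusted over the list alone (median 2.60, adjusted p = 1.17e-15, 0.0137 with an estimated correlation): Bhlhe40 by 7.65 ± 0.21, Zeb2 by 6.75 ± 0.17, Nfil3 by 4.76 ± 0.15, Prdm1 by 3.42 ± 0.15, Tox by 1.89 ± 0.25 and Eomes by 1.21 ± 0.11.

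Among receptors, migration genes rose in 12 of 23 and fell in 9 (median 0.90, camera adjusted p = 0.0241; adjusted p = 0.206 with an estimated correlation). Cytokine receptors rose in 11 of 18 and fell in 4 (median 1.02, adjusted p = 0.00601; adjusted p = 0.207 with an estimated correlation), the same counts adjusted over the list alone. The migration call was also lost within each set (adjusted p = 0.0508 in A and 0.0740 in B). Rgs16 rose by 5.84 ± 0.16 and Ccr9 changed by -5.61 ± 0.14. Costimulatory receptors did not pass (7 rose and 4 fell of 14, adjusted p = 0.0951), although Tnfrsf9, which encodes 4-1BB, rose by 4.42 ± 0.29, and nor did TCR signalling (4 and 9 of 22, 0.349), with 7 and 5, and 4 and 9, adjusted over the list alone. Interferon response genes fell in 17 of 27 and rose in 2 (18 and 2 adjusted over the list alone; median -0.60, adjusted p = 7.04e-05; adjusted p = 0.207 with an estimated correlation), with Oasl2 at -3.35 ± 0.20.

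Growth and metabolism lists rose. In mitosis 33 of 33 rose, also adjusted over the list alone (camera adjusted p = 9.41e-29, 0.0268 with an estimated correlation), with Ccna2 at 5.32 ± 0.16, Kif11 at 5.17 ± 0.15 and Mki67 at 5.10 ± 0.17. In DNA replication 29 of 31 rose (30 adjusted over the list alone; median 1.94, adjusted p = 1.56e-20, 0.0209 with an estimated correlation), with Rrm2 at 5.002 ± 0.18 and Cdc6 at 5.85 ± 0.24. In glycolysis 15 of 17 rose, also adjusted over the list alone (median 1.03, adjusted p = 1.11e-09, 0.0137 with an estimated correlation), with Tpi1 at 3.12 ± 0.16. In hypoxia 14 of 23 rose and 3 fell (16 and 4 adjusted over the list alone; median 0.70, adjusted p = 5.14e-04, 0.0137 with an estimated correlation), with Plin2 at 2.06 ± 0.12 and Pdk1 at -2.17 ± 0.084. Cholesterol synthesis rose in 12 of 16 (12 up and 1 down adjusted over the list alone; median 0.89, adjusted p = 4.80e-05; adjusted p = 0.131 with an estimated correlation; Cyp51 2.22 ± 0.18). The stress response rose in 19 of 27 with 2 falls (20 and 2 adjusted over the list alone; median 0.65, 1.50e-06; adjusted p = 0.114 with an estimated correlation; Asns 5.23 ± 0.28), and oxidative phosphorylation rose in 17 of 34 with 1 fall, the same adjusted over the list alone (median 0.30, 4.80e-05; adjusted p = 0.115 with an estimated correlation). The ribosome list did not pass (1 rose and 5 fell of 27, 0 and 3 adjusted over the list alone, adjusted p = 0.0642). It did pass without Tim-3+ replicate 2 (adjusted p = 0.0484), with the sets as a block (adjusted p = 0.0301) and within set B (adjusted p = 0.0305).

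Tim-3+ TIL against naive gave list medians, with the sets as a block, within set A and within set B, of -1.005, -1.57 and -0.87 for the stem-like and memory list, 3.12, 3.20 and 3.07 for cytotoxic effector genes, 2.89, 2.90 and 2.89 for inhibitory receptors, 2.61, 3.14 and 2.47 for transcription factors. They were 0.91, 1.08 and 0.75 for migration genes, 1.03, 0.98 and 1.05 for cytokine receptors, -0.54, -0.59 and -0.61 for interferon response, 4.34, 4.28 and 4.12 for mitosis, and 1.90, 1.78 and 1.93 for DNA replication. For the other lists past the threshold they were 1.02, 1.11 and 0.97 for glycolysis, 0.67, 0.64 and 0.70 for hypoxia, 0.91, 0.74 and 1.03 for cholesterol synthesis. Next came 0.65, 0.68 and 0.75 for the stress response, 0.28, 0.23 and 0.28 for oxidative phosphorylation, 0.57, 0.70 and 0.42 for dissociation genes, 1.53, 1.54 and 1.59 for CD4 and regulatory T cell markers, 0.68, 0.83 and 0.61 for NK cell markers, and -0.36, -0.52 and -0.22 for B cell markers. All 18 lists past the threshold passed with the sets as a block.

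Dissociation and immediate early genes moved here too: 15 of 25 rose and 5 fell, the same adjusted over the list alone, with a median of 0.56 (camera adjusted p = 3.99e-04; adjusted p = 0.114 with an estimated correlation). CD4 and regulatory T cell markers rose in 8 of 10 (8 up and 1 down adjusted over the list alone; median 1.53, adjusted p = 9.36e-06, 0.0118 with an estimated correlation), with Ikzf2 at 3.54 ± 0.19 while Foxp3, chosen after its values were seen, lay at 7.09 ± 0.18 in naive and 6.93 ± 0.16 in Tim-3+ cells (adjusted p = 0.291). NK cell markers rose in 4 of 8, also adjusted over the list alone (median 0.67, adjusted p = 0.00564, 0.0473 with an estimated correlation), with Gzma at 4.87 ± 0.32, and 4 of the 8 stand in other lists as well. B cell markers fell in 6 of 14, also adjusted over the list alone (median -0.35, adjusted p = 0.00564; adjusted p = 0.207 with an estimated correlation), with Ighm at -3.45 ± 0.13 and Cd79b at -3.29 ± 0.11. The others did not pass, with numbers risen and fallen and adjusted p of: melanoma (7 and 2 of 16, 0.234; Tyrp1 3.66 ± 0.57, Dct 2.92 ± 0.53), monocyte and macrophage (4 and 3 of 24, 0.622), dendritic cell (3 and 2 of 13, 0.611), neutrophil (2 and 0 of 10, 0.627; Ltf 3.17 ± 0.20), erythroid (0 and 0 of 6, 0.884), fibroblast and endothelium (1 and 3 of 17, 0.359; Pecam1 -3.06 ± 0.12) and keratinocyte (1 and 1 of 10, 0.758; Perp 6.95 ± 0.19). Adjusted over the list alone 3 rose and 1 fell in the dendritic cell list, and the other counts were the same. Tyrp1 and Dct were chosen after their values were seen. The melanoma genes named by the rule, Pmel and Trpm1, were lower in every Tim-3+ array than in any naive array. Pmel lay at 6.29 to 7.46 against 7.76 to 8.40 in naive arrays, and Trpm1 at 7.51 to 7.90 against 8.46 to 9.39. Both lay above the cut for background in naive cells, so their fall cannot exclude tumour RNA in the TIL sorts. Of the 16 melanoma members, 3 lay above that cut in naive, 5 in Tim-3- and 9 in Tim-3+ cells. The list mean, centred over all arrays, was 0.98, -0.25, 0.46 and 0.17 in Tim-3+ replicates 1 to 4. Naive arrays lay at -0.33 to -0.19. Tumour RNA as a source of changes was not tested and stays open. Median and mean had opposite signs for the monocyte and macrophage (-0.034 and 0.25), neutrophil (-0.18 and 0.62), erythroid (-0.00027 and 0.051) and keratinocyte (-0.046 and 0.60) lists. Fry but not camera passed monocyte and macrophage (0.0448), neutrophil (0.00369), fibroblast and endothelium (1.02e-04), keratinocyte (1.01e-05), ribosome (7.79e-04) and costimulatory receptor genes (6.17e-07).

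Both TIL groups shared most of their changes against naive cells. Bhlhe40, Zeb2, Klrc1 and Ctla4 were among the 2367 genes higher in both, and Ccr9, Dtx1 and Il6ra among the 2622 lower in both. Another 63 genes went opposite ways, Cxcr5 among them. Cxcr5 lay below 5.71 in naive and in Tim-3+ cells (5.69 and 4.68), so its fall between these may be a change within background. Independent calls would give 589 and 712 genes. Both comparisons use the same naive arrays. With these split between the comparisons in 20 ways, the median numbers were 1923 and 1877. With the sets as a block they were 2739 and 3150, and with a minimum of 2-fold 994 and 689. The log2 changes correlated across genes with r = 0.865, against 0.406 in 50 simulated pairs of unchanged groups with shared naive arrays, and their covariance was 0.701 against 0.0111.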

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

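The counts over splits of the arrays were planned before the data were examined, and the tests on the 2 sets of arrays, on Havcr2 and on the B cell genes were chosen only after the results were seen.

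The gene counts were set against those from other splits of the arrays into groups of the same sizes. The other splits mix the real groups, so a true difference widens their spread and lowers their counts. The rank of the real split therefore cannot exclude chance. For Tim-3+ against Tim-3- TIL, only the real split of 35 gave as many genes (1 split; real 2039 with these groups alone, highest other 306, the split that follows sets A and B). For Tim-3- TIL against naive the same held for 1 of 56 splits (real 5927, highest other 23, again the split that follows the sets). For Tim-3+ TIL against naive it held for 1 of 100 drawn splits (real 7606, highest other 3662). That other split differs from the real one only in naive replicate 1, which it puts with the 4 Tim-3+ arrays, and the split that follows the sets gave 65.

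Arrays of every group fell into 2 sets, A with the lower and B with the higher replicate numbers. Of the genes that changed between TIL groups, 99.9% stayed past the threshold with the sets as a block. The sets were drawn from the spread within groups of these same values, so the block lowers that spread by construction. Both sets also hold arrays of both TIL groups. Keeping the calls was therefore likely in advance, and this is no independent test of the sets as their source. For the sets themselves, a difference in RNA quality or amplification is a candidate explanation: the 3' minus 5' signal of 5 control transcripts was lower in set A by -0.248 (exact permutation within groups, two-sided p = 0.00556, the smallest the 180 arrangements can give). The sort day, which the labels give only as a range, was not tested and stays open, as does a biological difference between animals.

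Havcr2 was higher in Tim-3- TIL than in naive cells. Tim-3+ cells carried over into the Tim-3- sort would bring their granzymes along. The share of Havcr2 was 3.59% ± 1.37 (SD, n = 3) of the Tim-3+ signal above naive. At that share, Gzmc to Gzmg lacked a median of 1.73 ± 0.209 of the log2 level needed (SD over arrays, SE over members 0.639). For Gzmd, Gzme and Gzmg the level needed, 5.01, 5.64 and 4.70, lay below 5.71 and may itself be background. That cut is set over all genes, and these 3 read lower in naive cells, at 1.58, 2.37 and 4.49. For Gzmd and Gzme a rise to the level needed could therefore have been seen. Gzmf lay well below its needed level of 7.37 and Gzmc near its needed 6.14, so the test cannot decide on carry-over. The mean shortfall was 2.78 for Gzmf, 2.46 for Gzmd, 1.79 for Gzme and 0.619 for Gzmg, but 0.152 ± 0.510 for Gzmc, which carry-over could explain. Cd244a lacked 2.04, but the Tim-3- sort was also 2B4-, so the gate itself could keep it low. Of the measures tried, all after the results were seen, the median share of the 5 (0.312% ± 0.235) lay below that of Havcr2 by more than 2 times the SD over arrays, whereas the median gap in share over members, 3.22, was under 2 times its SE of 1.90, with Gzmg at -6.02% and Gzmc at 3.12%. Carry-over, as all or part of the signal, and Havcr2 transcription in cells without surface Tim-3 stay open.

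Ighm and Cd79b fell from naive over Tim-3- to Tim-3+ cells. B cells in the naive sort could give this, but would bring their other genes along, and the sort on CD8 should remove them. The other 12 members of the B cell list differed between Tim-3+ and naive cells by a median of -0.254 (SE of the median 0.136, range -1.10 to 0.023), against -3.45 and -3.29, which argues against B cells as the whole source. The abundant B cell genes Cd79a, Ms4a1 and Cr2 lay at 6.63, 3.70 and 5.82 in naive cells. Transcription of Ighm and Cd79b in T cells stays open, and no biological explanation was tested.

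Among naive and Tim-3+ arrays, a single array stood far from its group in 19 of 368 groups of values, 5.16%, where chance gives about 1 in 20. The Tim-3- arrays were not tested in this way. Over all genes, the SD of log2 differences from Tim-3- replicate 1 was 0.412 to replicate 2 and 0.400 to replicate 3. Between replicates 2 and 3 it was 0.256. The gap to the nearest array, over the group's range, was as follows. For Tim-3+ replicate 2 it was 0.941 for Ccl5, 0.836 for Chaf1b, 0.954 for Ctla4, 0.879 for Havcr2 and 0.948 for S100a4. For Tim-3+ replicate 1 it was 0.844 for Rasgrp2, 0.842 for Rps25 and 0.888 for the mean of the migration and residency list, and for Tim-3+ replicate 4 it was 0.984 for Il6ra and 0.837 for Nrp2. Among naive arrays it was 0.872 for Asns, 0.721 for Btla and 0.868 for Ccl5 in replicate 4, 0.762 for Ltf and 0.760 for Slamf7 in replicate 1, 0.742 for Mki67 and 0.744 for the ribosome list mean in replicate 2, and 0.721 for Cd8a and 0.786 for Pdcd1 in replicate 3. For Pdcd1 that array was at 5.68 with the others up to 5.07, and for Havcr2 Tim-3+ replicate 2 was at 11.87 with the others up to 11.61.

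Probe sets that the annotation gives no gene for were not used in the comparisons. Of 9160, 386 passed the threshold between the TIL groups, 2216 between Tim-3- TIL and naive, and 2792 between Tim-3+ TIL and naive.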

How the results depend on the processing

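Fits with sets A and B as a block or alone were chosen only after the results were seen; all other alternatives were planned. Of 120 counts under alternatives, 111 stayed within 1.5 times the reported one. Of 6025 values of named genes, 5850 kept their direction and side of the threshold, 127 lost a call, 34 gained one and 14 reversed, and of 1428 list results 1346 kept theirs, 55 lost a call and 27 gained one. A minimum of 2-fold, by its own construction, left 775 genes between the TIL groups, 2183 for Tim-3- and 2598 for Tim-3+ TIL against naive, and 1683 in both of these in 1 direction. Within set A, with fewer arrays, 1590 genes and 8 lists passed between the TIL groups. With an estimated correlation 2 lists passed between the TIL groups, 9 for Tim-3- and 9 for Tim-3+ TIL against naive. The estimate was well above the preset 0.01 for mitosis (0.432), DNA replication (0.264) and cholesterol synthesis (0.246). Hypoxia, with an estimate of -0.0215, lost its call between the TIL groups as well (camera p before adjustment 0.00293 preset, 0.00943 estimated). The CD4 and regulatory T cell list, with an estimate of -0.00268, went from 6.87e-10 to 1.19e-04 in Tim-3- TIL against naive. Both estimates lie below the preset, so higher correlation alone cannot account for the calls lost with an estimate. What else weakened them was not tested.

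Leaving out each array in turn gave 1666 to 2447 genes between the TIL groups, lowest without Tim-3- replicate 2, 5136 to 6046 for Tim-3- and 6858 to 7239 for Tim-3+ TIL against naive, and 11 to 15, 14 to 17 and 18 to 19 lists. Deviations of arrays of different groups correlated with r of 0.054 to 0.413 within a set and -0.385 to -0.122 across sets. The sets were drawn from these deviations, so this contrast is largely built in. Of 10 pairs with the same replicate number, the 8 above 0.1 lie within a set and the rest, at -0.15 and -0.13, across. With the number as a replicate block 2750, 6415 and 7681 genes passed, and as a random block 2854, 6721 and 8072 (consensus correlation 0.137).

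Named genes that reversed did so by the choice of probe set. With the most variable probe set, Cycs was at -0.20 and Pdia4 at -0.090 between the TIL groups, Cycs at -0.88, Hspa8 at -0.99 and Ms4a6c at -1.25 in Tim-3- TIL against naive, and Cycs at -1.08, Rps6 at 1.14, Hspa8 at -1.01, Jund at -0.62 and Prf1 at 2.74 in Tim-3+ TIL against naive. With the mean of all probe sets, Ms4a6c was at -0.51 in Tim-3- TIL, and Rps6 at 0.40, Jund at -0.10 and Prf1 at 1.12 in Tim-3+ TIL against naive. Signal over background limits dim genes: with a filter on them, 2312 of 10916 genes passed between the TIL groups.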

Other observations

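The groups below were set by their order after the values were seen. A total of 434 genes were highest in Tim-3- TIL, past the threshold against both other groups, and 165 of them by at least 2-fold on both sides. Among those with the largest smaller step were Synpo, at 5.65 in naive, 10.97 in Tim-3- and 6.29 in Tim-3+ cells, and the chemokine receptor Ccr6, at 4.88, 9.23 and 4.68. Adh4 (3.08, 7.24 and 3.04), Dnase1l3 (4.60, 8.28 and 4.63) and Cd24a (5.28, 8.67 and 4.72) followed. Tnfsf11 (4.29, 11.35 and 8.40), the activation marker Cd83 (5.87, 10.41 and 7.55), Cxcr5 (5.69, 8.51 and 4.68) and its ligand Cxcl13 (5.15, 7.75 and 5.37) belonged to the group too.

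Other orders were a rise from naive over Tim-3- to Tim-3+ cells in 601 genes (196 with both steps at least 2-fold), a fall over the same steps in 309 (81), and levels lowest in Tim-3- cells in 273 (18). Tim-3+ cells stood above both other groups in 1103 genes (334 by at least 2-fold on both sides) and below both in 616 (202), and these counts take in genes of the rise and fall.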
